A study of Mus musculus with 6 samples.

How the data were processed

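RNA was sequenced from 6 colonic tumor samples of AOM/DSS-treated mice, 3 GRwt and 3 GRdim. Per the labels, total RNA was extracted with the RNeasy kit, polyadenylated RNA was taken up with the Dynabeads mRNA DIRECT kit and libraries were made with the Illumina Stranded mRNA Prep kit. The authors converted base calls with bcl2fastq 2.20.0.422, trimmed reads with Trim Galore, checked them with FastQC and MultiQC, aligned them with STAR 2.7.8a to the mouse build GRCm39, counted them with featureCounts of Subread 1.5.0 and tested them with DESeq2 1.40.2. The deposited table holds raw read counts per gene with no normalization: all values were whole numbers and the library totals differed. The annotation release, the strand setting and any filter on the table's genes are not given in the labels. Gene positions were taken from the deposited table.

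The table held 24797 genes, of which 813 had a count of 0 in all 6 libraries. Library totals ran from 21132981 to 36222351 counts. Library columns were matched to samples by the library name that each sample's description gives. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM normalization, the default filter on low counts by group and robust dispersion estimation. This left 18756 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM values are counts divided by the TMM-scaled library total; list scores used log2 CPM with a prior count of 2. The standard error of a log2 fold change is its size divided by the square root of its F statistic. The common biological coefficient of variation was 0.330 and the median standard error of the log2 fold change 0.29. Fold changes are GRdim relative to GRwt. Intervals on counts are exact 95% intervals and cover counting error only.

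Before the data were examined, 40 gene lists with 695 genes were fixed for epithelial, immune, stromal and surrounding-tissue markers and for signalling and stress programs, together with the tests, the rule for naming genes and the alternatives. Of the listed genes 644 were tested, and 39 lists had at least 5 tested members; the list of sex-linked genes had too few. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. It was also tested on its own with fry, for a shift in 1 direction and for changes in either direction. 20 lists passed with the preset correlation, 10 higher and 10 lower in GRdim; 0 passed with the estimated correlation. At the same settings 0 passed fry in 1 direction and 2 passed in either direction. Several lists share genes, among them Lcn2, Nos2, Mmp7, Mmp8, Mmp9 and Il1r2. Lists of cell type markers in bulk tissue give transcript levels, not cell numbers.

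The naming rule took Nr3c1; genes past the threshold with a mean of at least 1 CPM and no overlap between genotypes, or, where fewer passed, up to 6 genes per direction of smallest p, said not to pass; up to 4 members of smallest p in each list described; receptor targets that pass; and sex-linked genes. Gene models without a gene name and antigen receptor segments were passed over. A gene named outside this rule is said to have been chosen after its values were seen.

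The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression size factors, no filter on low counts, the T in the library names as a covariate, GRdim replicates 1 and 3 summed as 1 sample, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were the 4 libraries with no T in their names alone, DESeq2 with the T as a covariate, and unadjusted p for genes near Nr3c1. Sex as a covariate was planned only for the case of both sexes in both genotypes, and was not run because GRdim replicate 2 alone carried Y-linked transcripts.

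The procedure was tested on data simulated with 200 changed genes in each of 5 runs. With edgeR it recovered 16.7% of genes changed 2-fold, 66.3% of those changed 4-fold and 86.4% of those changed 8-fold, and called 0.0356% of unchanged genes. Apart from the planted changes each gene had the same expected level in every library, without the differences between libraries described below. The recovered shares may therefore not hold for these samples. A neutrophil list planted 2-fold lower was called by camera in 5 of 5 runs with the preset correlation and in 0 of 5 with the estimated one, and 0 of 190 tests of other lists were called. The simulated genes varied independently, so these runs do not test calls on lists whose members vary together. In the tumor libraries the estimated correlations ran from -0.056 for p53 targets to 0.95 for B cell markers.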

Results

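Polyadenylated RNA was sequenced from 6 colonic tumor samples of mice given AOM/DSS, that is azoxymethane, a colon carcinogen, followed by dextran sulfate sodium, which injures the colonic epithelium and causes colitis. 3 samples came from mice with the wildtype glucocorticoid receptor (GRwt) and 3 from mice carrying a receptor that is deficient in dimerization (GRdim). The glucocorticoid receptor is the hormone-activated transcription factor through which cortisol or corticosterone acts. The single comparison of the design asks how the transcripts of such tumors differ when dimerization of the receptor is impaired. Total counts were 34081382, 21132981 and 36222351 in GRwt replicates 1, 2 and 3 and 26934082, 33667375 and 26073007 in GRdim replicates 1, 2 and 3. The labels do not say that the samples of a genotype came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

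The libraries also differed in ways that genotype did not account for. GRwt replicate 3 and GRdim replicate 1 carry a T in their library names, and in them the ribosomal sequence Rn18s-rs5 took 2.51% and 2.05% of the counts, against 0.0466% to 0.0725% in the other 4 libraries. These 2 libraries had a correlation across genes of 0.984, above every other pair, and lay together on the first principal component, which held 37.8% of the variance. Since each genotype had 1 of them, list values among the 4 other libraries are given where a call changed or the median of a list that passed moved by over 1.5 times. For list medians that factor is taken on the log2 values themselves. GRdim replicate 2 held the Y-linked transcript Ddx3y at 62.4 CPM (2101 counts) and Xist, the transcript of the inactive X chromosome, at 0.267 CPM (9 counts), CPM here being relative to the plain library total. The other 5 libraries held Xist at 539.9 to 1277 CPM and Ddx3y at no more than 0.71 CPM. GRdim replicates 1 and 3 have library names with a shared number, and the labels do not say whether they came from 1 animal.

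**Figure D1:**
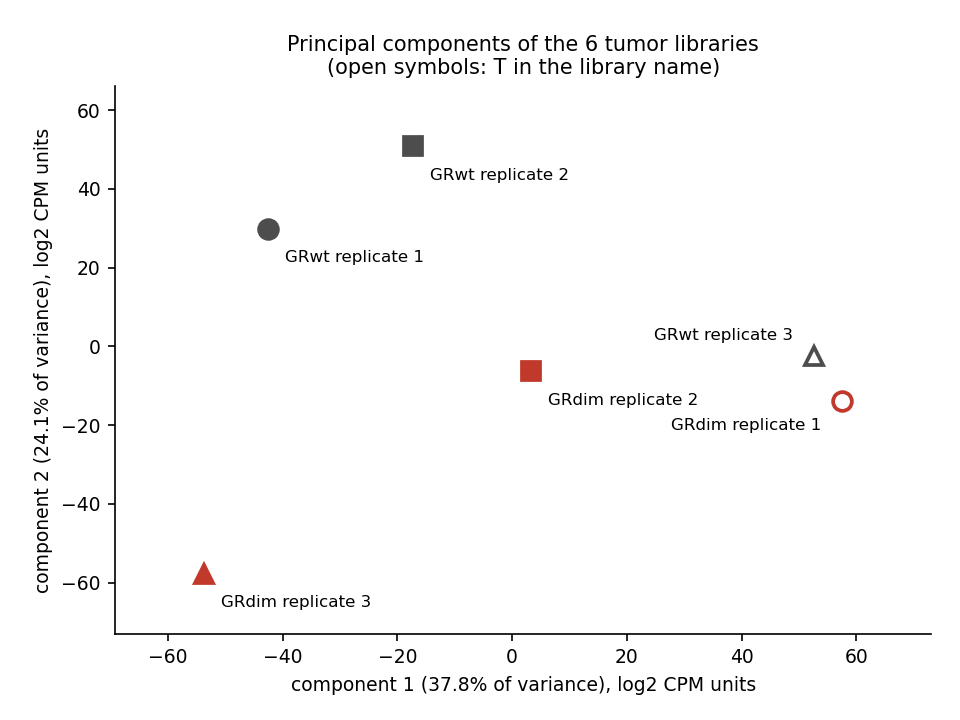
Principal components of log2 CPM over 18756 genes, with component 1 on the x axis (37.8% of the variance) and component 2 on the y axis (24.1%), both in log2 CPM units; each symbol is 1 tumor library, grey for GRwt and red for GRdim, and open symbols mark the 2 libraries with a T in their names. The 2 open symbols lie side by side although they are of different genotypes, and GRdim replicate 3 lies apart at the lower left.

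The transcript of Nr3c1, the gene of the glucocorticoid receptor (chromosome 18, 39543598 to 39652474, minus strand, GRCm39), stood at 55.3 ± 10.5 CPM in GRwt and 59.6 ± 18.1 CPM in GRdim tumors (mean ± SD, n = 3 per group). The log2 fold change, given throughout as GRdim minus GRwt, was 0.11 with a standard error of 0.25. Without GRwt replicate 1 it was -0.03, and without GRdim replicate 1 -0.17. An exact two-sided permutation test of log2 CPM gave p = 0.8, where 0.1 is the smallest p that 3 samples against 3 allow. The GRdim allele is a point mutation, so the level of this transcript does not check the genotype labels.

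GRdim tumors held less of the transcripts of neutrophil chemoattractants, interleukin-1 and other mediators of acute inflammation. Cxcl1, a chemokine that attracts neutrophils (chromosome 5, 91039100 to 91040974), stood at 18.4 ± 3.79 CPM in GRwt and 6.37 ± 0.603 CPM in GRdim tumors (mean ± SD, n = 3 per group), 2.89 times lower. Il1b and Il1a, the genes of both forms of interleukin-1, stood at 32.7 ± 9.14 and 9.44 ± 1.85 CPM in GRwt against 11.1 ± 3.44 and 2.34 ± 1.07 CPM in GRdim tumors. Cxcl3, a further neutrophil chemokine, stood at 3.29 ± 0.206 against 0.759 ± 0.339 CPM. All 4 were lower in every GRdim library than in any GRwt library. Of the 28 tested genes of the inflammatory cytokine and NF-kB list, 20 were lower and 8 higher in GRdim tumors. With edgeR, 10 of the lower ones and 0 of the higher ones had an unadjusted p under 0.05. None passed when adjusted over all genes tested, and 7 passed when adjusted over the list alone, namely the 4 above with Il11, Cxcl2 and Ptgs2, named after their values were seen. Il11, an interleukin-6 family cytokine, stood at 35.3 ± 9.65 against 7.84 ± 4.301 CPM, and Ptgs2, the inducible cyclooxygenase, at 58.3 ± 34.7 against 17.2 ± 4.701 CPM. The NF-kB pathway genes Nfkb2, Relb and Nfkbia, likewise chosen after their values were seen, had log2 fold changes of 0.11, 0.24 and 0.10, each smaller than its standard error of 0.18, 0.26 and 0.17. The list had a median log2 fold change of -0.58 and was lower in GRdim by camera with a preset correlation (adjusted p = 2.02e-12). That call was lost with the correlation estimated from the data (adjusted p = 0.160 with an estimated correlation). Fry's test for a shift in 1 direction did not pass either (adjusted p = 0.139), while its test for changes in either direction gave an adjusted p of 0.00305. The median was -0.38 without GRdim replicate 1, -0.34 among the 4 libraries with no T in their names and -0.35 with limma-voom on all 6 libraries.

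**Figure D2:**
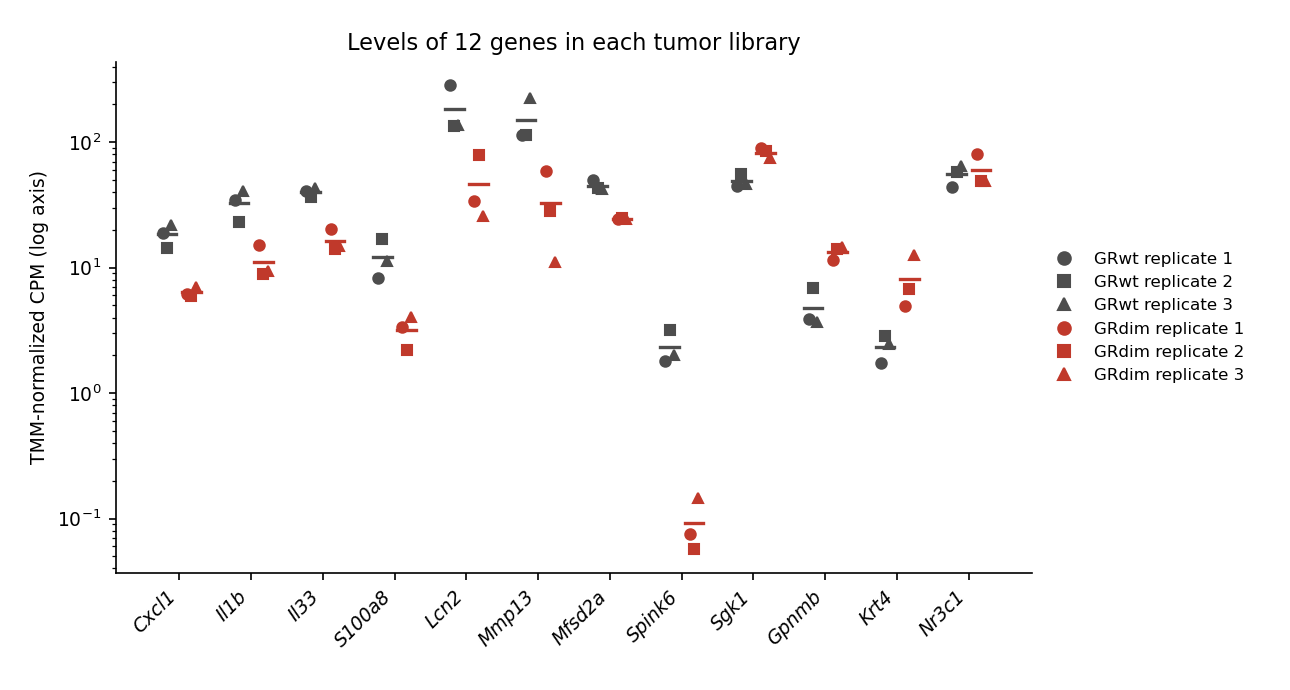
TMM-normalized CPM on a log axis (y axis) of 12 named genes (x axis) in each tumor library; grey symbols are GRwt, red symbols GRdim, symbol shapes replicates, and bars the group means of 3 libraries. Cxcl1, Il1b, Il33, S100a8, Lcn2, Mmp13, Mfsd2a and Spink6 lie lower in each GRdim library than in any GRwt library, Sgk1, Gpnmb and Krt4 higher, and Nr3c1 overlaps between the genotypes. Genes taken by smallest p across the transcriptome, such as Mfsd2a, Spink6 and Gpnmb, were named only where the genotypes did not overlap. Of all tested genes 6.55% did not overlap, where chance gives 10%.

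Neutrophil transcripts were lower in each GRdim tumor as well. S100a8, a calcium-binding protein abundant in neutrophils, stood at 12.2 ± 4.45 CPM in GRwt and 3.19 ± 0.909 CPM in GRdim tumors, 3.82 times lower, and Csf3r, the receptor for granulocyte colony-stimulating factor, at 11.4 ± 3.34 against 5.65 ± 0.927 CPM. The formyl peptide receptors Fpr2 and Fpr1 stood at 1.64 ± 0.409 and 0.890 ± 0.371 against 0.577 ± 0.159 and 0.197 ± 0.141 CPM, levels that rest on few reads. Of the 16 tested neutrophil markers 14 were lower and 2 higher, 8 of the lower ones at an unadjusted p under 0.05, and 3 passed in edgeR when adjusted over the list alone (S100a8, Csf3r and Fpr2). The median log2 fold change was -1.28, with a camera adjusted p of 2.77e-13 with a preset correlation and 0.160 with an estimated correlation. Fry's test gave an adjusted p of 0.139 for a shift in 1 direction and 0.0406 for changes in either direction. Measured as the mean log2 CPM of the list relative to the GRwt mean, GRdim replicates 1, 2 and 3 lay at -0.85, -1.37 and -0.82, and the GRwt replicates between -0.21 and 0.25. Macrophage and monocyte transcripts did not move with them: 9 of 19 tested markers were higher and 10 lower, and the list did not pass (adjusted p = 0.890), although without GRwt replicate 1 it passed as higher (median 0.21, adjusted p = 0.0191). Within that list Cd14, the lipopolysaccharide coreceptor, stood at 145 ± 30.4 against 97.2 ± 13.96 CPM, and Mrc1, the mannose receptor, at 16.6 ± 2.45 against 21.5 ± 5.98 CPM.

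Antimicrobial and tissue-remodelling transcripts were lower as lists. Lcn2, the iron-sequestering lipocalin released by inflamed epithelium, stood at 185 ± 85.4 CPM in GRwt and 46.2 ± 28.3 CPM in GRdim tumors, and Saa3, an acute-phase protein, at 59.96 ± 37.2 against 12.04 ± 7.43 CPM. Duox2 and Nos2, which make hydrogen peroxide and nitric oxide, stood at 372 ± 126 and 60.99 ± 25.8 against 206 ± 31.7 and 31.1 ± 7.23 CPM. In the list of Paneth and antimicrobial epithelial genes 14 of 16 tested members were lower, 2 of them (Lcn2 and Saa3) when adjusted over the list alone. The list median was -0.80 (camera adjusted p = 1.26e-10; adjusted p = 0.316 with an estimated correlation). Its score in GRdim replicate 2, -0.32, lay within the GRwt range of -0.46 to 0.45, whereas GRdim replicates 1 and 3, both high in smooth muscle (1.13 and 2.09) and adipocyte markers (3.59 and 2.87), lay at -1.49 and -1.25. GRwt replicate 1, with an adipocyte score of 1.86 and a smooth muscle score of -0.10, lay at 0.45. The collagenase Mmp13 stood at 151 ± 63.4 against 32.8 ± 24.3 CPM and the stromelysins Mmp10 and Mmp3 at 253 ± 65.2 and 14.999 ± 4.58 against 63.98 ± 46.4 and 5.52 ± 2.88 CPM. Among the 14 matrix metalloproteinases and their inhibitors 8 were lower and 6 higher, and Mmp13 and Mmp10 passed when adjusted over the list alone. That list had a median of -0.69 (camera adjusted p = 3.39e-04; adjusted p = 0.234 with an estimated correlation), and -0.31 without GRwt replicate 1. Single libraries moved the fold change of some of these genes by over 1.5 times on the unlogged scale: Lcn2 had a log2 fold change of -2.002, and -2.63 without GRdim replicate 2. Saa3 had -2.32, and -1.69 without GRwt replicate 1. Mmp13 and Mmp10 had -2.200 and -1.99, and -2.94 and -2.64 without GRdim replicate 1.

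Il33, an alarmin cytokine kept in nuclei of barrier and stromal cells (chromosome 19, 29902514 to 29938118), stood at 40.1 ± 3.18 CPM in GRwt and 16.4 ± 3.52 CPM in GRdim tumors (mean ± SD, n = 3 per group), 2.45 times lower. Il1rl1, which encodes its receptor chain and was chosen after its values were seen, stood at 189 ± 52.6 against 65.6 ± 20.7 CPM. Il33 belonged to the fixed list of fetal-type regenerative epithelium, where 18 of 20 members were lower and Il33 alone passed when adjusted over the list alone. Spp1 and Ereg, the genes of osteopontin and the growth factor epiregulin, stood at 49.5 ± 28.9 and 64.02 ± 24.6 against 19.9 ± 8.94 and 34.6 ± 10.5 CPM. The list median was -0.26 (camera adjusted p = 3.77e-06; adjusted p = 0.334 with an estimated correlation) and -0.09 without GRwt replicate 1 or -0.14 without GRdim replicate 1, and -0.39 without GRdim replicate 3.

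All 25 proliferation genes were lower in GRdim tumors, by small amounts. The replication licensing genes Mcm3 and Mcm2 stood at 65.4 ± 6.83 and 66.7 ± 4.34 CPM in GRwt against 46.9 ± 6.44 and 51.6 ± 3.55 CPM in GRdim tumors, and none of the 25 passed when adjusted over the list alone. The list median was -0.25 (camera adjusted p = 1.57e-08; adjusted p = 0.316 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.25, with 17 of 19 lower (camera adjusted p = 2.57e-06; adjusted p = 0.334 with an estimated correlation). Without GRwt replicate 2 that median was -0.16, and without GRwt replicate 3 -0.39. Goblet cell markers were lower in 19 of 20 cases with a median of -0.41 (camera adjusted p = 5.20e-07; adjusted p = 0.449 with an estimated correlation). Agr2, a disulfide isomerase of mucus-secreting cells, stood at 1346 ± 171 against 779 ± 379 CPM. The goblet call rested on GRdim replicate 3, whose score lay -1.59 from the GRwt mean on the log2 scale: without it the median was -0.13 and the list did not pass (adjusted p = 0.328). That library also had the highest smooth muscle and squamous scores (2.09 and 2.27). GRdim replicate 1, with a smooth muscle score of 1.13, had a goblet score of 0.04. The goblet median was -0.27 without GRwt replicate 2, -0.72 without GRdim replicate 1 and -0.86 among the 4 libraries with no T in their names. Mitochondrially encoded transcripts had a median of -0.25 (camera adjusted p = 0.00110; adjusted p = 0.510 with an estimated correlation) and did not pass without GRwt replicate 3, GRdim replicate 2 or GRdim replicate 3 (medians -0.11, -0.14 and -0.21), while the median was -0.39 without GRwt replicate 2, -0.64 without GRdim replicate 1 and -0.53 among the 4 libraries with no T in their names.

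Absorptive colonocyte markers, Wnt/beta-catenin targets and intestinal stem cell markers did not pass (adjusted p = 0.0972, 0.243 and 0.675). The Wnt list passed as higher without GRwt replicate 1 or GRdim replicate 1 (medians 0.35 and 0.30). Its median was -0.05 without GRwt replicate 2, -0.02 without GRwt replicate 3 and -0.04 without GRdim replicate 3, and there it did not pass. The colonocyte list passed as lower without GRwt replicate 1 or 3 and without GRdim replicate 1 or 2 (medians -0.27, -0.27, -0.27 and -0.12) but as higher without GRwt replicate 2 (0.24). Among the 4 libraries with no T in their names the Wnt list passed as higher (0.21, adjusted p = 0.00151) and the colonocyte list as lower (-0.48, adjusted p = 1.92e-04). With no library left out, the Wnt list passed as higher with limma-voom and with GRdim replicates 1 and 3 summed (adjusted p = 0.0223 and 0.0164), and the colonocyte list as lower with DESeq2 and limma-voom (adjusted p = 0.0418 and 0.00123). Members of the colonocyte list went both ways: Clca4b stood at 838 ± 186 against 393 ± 108 CPM, and Scnn1g, a subunit of the epithelial sodium channel, at 2.79 ± 0.864 against 5.699 ± 1.96 CPM. Clca4b has a close paralog, Clca4a, so the division of reads between them is uncertain. The Wnt antagonists Nkd2 and Apcdd1, both induced by Wnt signalling, stood at 1.88 ± 0.120 and 107 ± 36.3 against 5.03 ± 2.64 and 228 ± 121 CPM, and Lgr5, the stem cell receptor, at 62.4 ± 34.4 against 37.4 ± 12.6 CPM. Dkk2, a further member of the Wnt list, went the other way from Nkd2 and Apcdd1, at 40.1 ± 6.93 against 28.5 ± 3.82 CPM.

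Transcripts of antigen presentation, lymphocytes and the interferon response were higher in GRdim tumors as lists, with no single gene of these lists past the threshold in edgeR over all genes. Adjusted over the list alone, only Iglc1 of the plasma cell markers, described below, passed. In the MHC class II pathway 10 of 11 members were higher with a median of 0.50 (camera adjusted p = 5.20e-07; adjusted p = 0.334 with an estimated correlation). H2-Aa, a class II chain, stood at 116 ± 28.6 CPM in GRwt and 165 ± 25.99 CPM in GRdim tumors, and the list median was 0.32 without GRdim replicate 2. Relative to the GRwt mean, class II scores lay at -0.03, -0.45 and 0.49 in GRwt replicates 1, 2 and 3 and at 0.55, 1.097 and 0.40 in GRdim replicates 1, 2 and 3. GRwt replicate 3 and GRdim replicate 2, the highest of their genotypes, were also the highest in B cell markers (2.11 and 2.31). Interferon-response genes were higher in 22 of 28 cases with a median of 0.33 (camera adjusted p = 2.73e-06; adjusted p = 0.449 with an estimated correlation). Mx2, Rsad2 and Ifit1, antiviral effectors, stood at 5.005 ± 1.601, 9.901 ± 2.84 and 29.5 ± 7.21 against 10.1 ± 1.94, 20.6 ± 7.95 and 51.4 ± 13.7 CPM, while Cxcl9, a T cell chemokine, stood at 9.18 ± 3.298 against 4.22 ± 1.81 CPM. Among the 4 libraries with no T in their names the interferon list had a median of 0.13 and did not pass (adjusted p = 0.416), and without GRdim replicate 1 the median was 0.14, without GRwt replicate 1 0.50. T and NK cell markers had a median of 0.35 with 22 of 25 higher (camera adjusted p = 3.39e-04; adjusted p = 0.449 with an estimated correlation). Cd3e, part of the T cell receptor complex, stood at 1.72 ± 0.206 against 2.76 ± 0.167 CPM. Without GRdim replicate 2 the T and NK median was 0.17 and the list did not pass (adjusted p = 0.216), nor did it without GRwt replicate 2 (median 0.17, adjusted p = 0.0505).

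B cell markers were all higher, 15 of 15, with a median of 0.71 (camera adjusted p = 5.01e-08; adjusted p = 0.449 with an estimated correlation), but none had an unadjusted p under 0.05. Their scores varied within each genotype: relative to the GRwt mean, GRwt replicates 1, 2 and 3 lay at -1.07, -1.04 and 2.11 and GRdim replicates 1, 2 and 3 at 1.41, 2.31 and 0.41 on the log2 scale. Cd79a, part of the B cell receptor complex, stood at 11.2 ± 10.4 against 19.9 ± 12.98 CPM. Leaving out libraries moved the B cell median: it was 0.31, 0.34 and 2.63 without GRwt replicates 1, 2 and 3, 0.83, 0.14 and 1.06 without GRdim replicates 1, 2 and 3, and 2.73 among the 4 libraries with no T in their names. With no library left out it was 2.03 with limma-voom, 1.61 with the replicate number as a block and 1.53 with the T as a covariate. Plasma cell markers and MHC class I genes had medians of 0.31 and 0.18 (camera adjusted p = 0.0346 and 0.0144; adjusted p = 0.510 and 0.533 with an estimated correlation). Among plasma cell markers the immunoglobulin light chain gene Iglc1 passed when adjusted over the list alone (41.6 ± 7.195 against 117 ± 64.6 CPM); its reads may be shared with its close paralogs, and it was chosen after its values were seen. The plasma cell call was lost without GRwt replicate 1 or 3 and without GRdim replicate 1 or 2 (medians -0.01, 0.24, 0.23 and 0.08). The class I call was lost without GRwt replicate 3 or GRdim replicate 3 (medians -0.05 and 0.05), and its median was 0.40 without GRwt replicate 1. Among the 4 libraries with no T in their names neither list passed (plasma cell median 0.19, adjusted p = 0.243; class I median 0.02, adjusted p = 0.888). With no library left out, the plasma cell call was lost with limma-voom or with the T as a covariate (adjusted p = 0.0647 and 0.0832). The class I call was lost with DESeq2, with limma-voom and with GRdim replicates 1 and 3 summed (adjusted p = 0.0660, 0.190 and 0.0731).

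**Figure D3:**
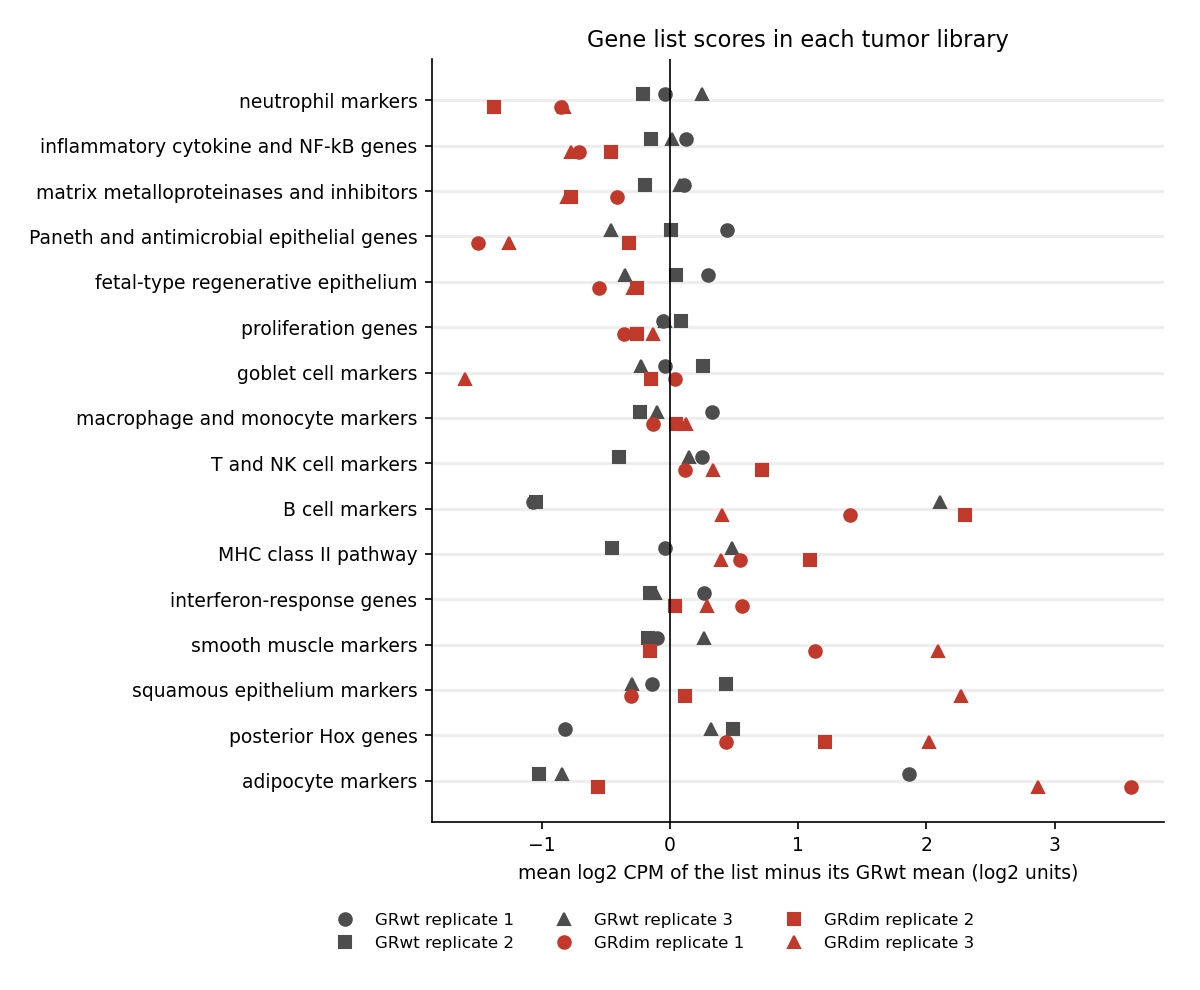
Mean log2 CPM of the tested members of 16 gene lists in each tumor library, relative to the mean of the 3 GRwt libraries (x axis, log2 units; 1 row per list); grey symbols are GRwt, red symbols GRdim and shapes mark replicates. The neutrophil, inflammatory, metalloproteinase and proliferation scores of all 3 GRdim libraries lie to the left of every GRwt library, whereas smooth muscle, squamous and Hox scores are highest in GRdim replicate 3 (2.09, 2.27 and 2.02).

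Transcripts of tissues that can surround a colonic tumor varied between libraries of 1 genotype as well as between genotypes. All 14 smooth muscle markers were higher in GRdim tumors with a median of 1.23 (camera adjusted p = 2.14e-11; adjusted p = 0.387 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, stood at 586, 219.9 and 1273 CPM in GRdim replicates 1, 2 and 3 and at 233 ± 71.7 CPM in GRwt tumors (mean ± SD, n = 3). Without GRdim replicate 3 the list median was 0.56, and with limma-voom on all 6 libraries 0.76. Squamous epithelium markers had a median of 1.198 (camera adjusted p = 0.0132; adjusted p = 0.533 with an estimated correlation), which was -0.23 without GRdim replicate 3, and the call was also lost without GRwt replicate 3 (adjusted p = 0.223) and among the 4 libraries with no T in their names (median 1.63, adjusted p = 0.0671). On all 6 libraries the squamous call was lost with limma-voom or with the T as a covariate (medians 0.82 and 1.01, adjusted p = 0.0790 and 0.0832). The epidermal keratins Krt10 and Krt6a stood at 142 and 60.9 CPM in GRdim replicate 3 and at no more than 5.65 and 2.44 CPM in the other 5 libraries. Krt6a reads may be shared with its close paralog Krt6b. Krt4, a keratin of nonkeratinized squamous epithelium, was higher in each GRdim library, at 2.34 ± 0.570 against 8.05 ± 3.95 CPM. Posterior Hox genes had a median of 1.13 (camera adjusted p = 0.00961; adjusted p = 0.449 with an estimated correlation), 0.45 without GRdim replicate 3, and did not pass without GRwt replicate 3 (adjusted p = 0.105). The members at an unadjusted p under 0.05 were all of the Hoxd cluster, and Hoxd12 passed when adjusted over the list alone: it stood at 3.18, 17.03 and 48.8 CPM in GRdim replicates 1, 2 and 3 against 1.29 ± 0.996 CPM in GRwt tumors. Its log2 fold change was 4.21, 4.86 without GRwt replicate 2 and 3.01 without GRdim replicate 3. Adipocyte markers had a median of 2.41 (camera adjusted p = 0.00449; adjusted p = 0.510 with an estimated correlation), with scores of 1.86 in GRwt replicate 1, 3.59 in GRdim replicate 1 and 2.87 in GRdim replicate 3 against -1.02 to -0.56 in the other 3. The adipocyte call was lost without GRwt replicate 3 or GRdim replicate 1 (medians 1.796 and 1.19), and the median was 4.82 without GRwt replicate 1 and 0.79 among the 4 libraries with no T in their names, where the list did not pass. It was also lost with limma-voom on all 6 libraries (median 1.46, adjusted p = 0.133).

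The fixed list of glucocorticoid receptor targets did not pass in either direction (median -0.19, camera adjusted p = 0.0849; adjusted p = 0.533 with an estimated correlation). Of its 35 tested genes 13 were higher and 22 lower in GRdim tumors. Sgk1, a kinase that regulates sodium transport, was higher in each GRdim tumor (49.1 ± 5.82 against 82.6 ± 7.51 CPM), and passed when adjusted over the list alone, as did Lcn2 and Cebpb, both lower. Cebpb, a transcription factor of acute inflammation, stood at 26.9 ± 4.44 against 15.2 ± 1.96 CPM, and Tgm2, a transglutaminase, at 205 ± 42.3 against 128 ± 11.2 CPM. Fkbp5, Tsc22d3 and Per1, widely used readouts of the receptor and chosen here after their values were seen, stood at 39.8 ± 8.82, 34.2 ± 10.2 and 22.3 ± 3.6004 against 32.2 ± 10.8, 40.9 ± 4.39 and 30.4 ± 1.26 CPM. The list passed as lower without GRwt replicate 3 or GRdim replicate 2 (medians -0.31 and -0.30) and among the 4 libraries with no T in their names (-0.31), and with limma-voom on all 6 (-0.26, adjusted p = 0.0358). Its median was -0.05 without GRwt replicate 1, -0.05 without GRwt replicate 2 and -0.09 without GRdim replicate 3, and there the list did not pass. The list of glucocorticoid synthesis and receptor genes had a median of -0.23 (camera adjusted p = 0.0417, and adjusted p = 0.387 with an estimated correlation). That call was lost without GRwt replicate 2 or 3 and without GRdim replicate 2 or 3 (medians -0.13, -0.26, -0.19 and -0.13), and the median was -0.55 without GRdim replicate 1 and -0.48 among the 4 libraries with no T in their names. On all 6 libraries it was also lost with DESeq2 or with the T as a covariate (adjusted p = 0.0669 and 0.0622). Hsd11b2, the enzyme that inactivates corticosterone, stood at 295 ± 124 against 219.7 ± 89.95 CPM.

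Across the transcriptome no single gene passed. With edgeR's quasi-likelihood test 0 of 18756 genes had a Benjamini-Hochberg adjusted p under 0.05, the smallest being 0.518 for Spink6, and 541 had an unadjusted p under 0.05, 336 higher and 205 lower. Leaving out 1 library kept the count past the adjusted threshold at 0, while the unadjusted count was 322, 332 and 995 without GRwt replicates 1, 2 and 3 and 1048, 787 and 245 without GRdim replicates 1, 2 and 3. Groups without overlap were found for 6.55% of the tested genes, where chance gives 10%. DESeq2 called 33 genes, 10 higher and 23 lower, and limma-voom with sample quality weights called 0, with 747 and 903 at an unadjusted p under 0.05. Of the 10 splits of the 6 libraries into groups of 3, 5 gave at least as many DESeq2 calls, the genotype split included. The others among these put both T libraries in 1 group (115, 708, 47 and 479 calls). The splits that kept the T libraries apart, as the genotype split does, gave 9, 1, 4, 0 and 21 calls. With so few splits, the DESeq2 calls below do not by themselves mark differences between genotypes. Of the genes named above DESeq2 called Cxcl1, Il33, S100a8, Il1a, Il1b, Il1rl1, Il11, Cxcl3, Lcn2, Cxcl2, Mmp13, Ptgs2, Saa3, Clca4b and Mmp10 as lower and Krt4 and Iglc1 as higher, with DESeq2 adjusted p from 2.64e-05 for Cxcl1 to 0.0457 for Iglc1. The naming rule took the 6 genes per direction of smallest p in edgeR whose libraries did not overlap between genotypes. Those of them outside the lists were Spink6, Serpine2 and Mfsd2a, all lower, and Gpnmb, Trim58, Ccl21a and Chrdl1, all higher, and none of them passed in edgeR. Spink6, a Kazal-type protease inhibitor (ENSMUSG00000055095, chromosome 18, 44204460 to 44216678), stood at 2.33 ± 0.721 CPM in GRwt and 0.0928 ± 0.0477 CPM in GRdim tumors, from 196 counts against 8, a ratio of 24.4 with a 95% exact counting interval of 12.2 to 57.4 that covers counting error only. Serpine2, an inhibitor of thrombin and urokinase, stood at 57.1 ± 6.89 against 24.7 ± 5.34 CPM, and Mfsd2a, a transporter of lysophosphatidylcholine carrying omega-3 fatty acids, at 45.1 ± 4.298 against 24.6 ± 0.432 CPM. Gpnmb, a lysosomal and cell surface glycoprotein of macrophages, stood at 4.79 ± 1.76 against 13.4 ± 1.73 CPM, and Chrdl1, an antagonist of bone morphogenetic proteins, at 2.23 ± 0.466 against 8.49 ± 4.47 CPM. Trim58, a ubiquitin ligase of the red cell lineage, stood at 0.443 ± 0.153 against 2.401 ± 1.203 CPM, and Ccl21a, a chemokine of lymphoid tissue whose reads may be shared with near-identical gene copies, at 11.8 ± 1.28 against 26.4 ± 8.33 CPM. DESeq2 called all 7.

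Genes close to Nr3c1 on chromosome 18 were examined because sequence linked to an altered locus can stay with it through breeding. Of 194 tested genes within 10 Mb of Nr3c1, 0 passed with edgeR and 4 had an unadjusted p under 0.05, a share of 2.06% (exact 95% interval 0.565% to 5.19%) against 2.89% of all other tested genes. The 4 were Spink6, Smim33, Myot and Cd14, all lower in GRdim tumors, at distances of 4.66, 3.71, 4.92 and 2.69 Mb. Within 5 Mb the share was 2.96% against 2.88% of all other tested genes, and within 20 Mb 2.61% against 2.89%. DESeq2 called Spink6 in that window (adjusted p = 2.28e-06).

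For macrophage, fibroblast, erythroid, proximal colon, xenobiotic and lipid handling lists, none of which passed, the median, the mean and the camera direction differed in sign. Immune checkpoint genes, p53 targets, genes of proximal colon, ileum and stomach, and lipid handling genes did not pass and also stayed short of the threshold when any single library was left out (adjusted p with all libraries 0.201, 0.244, 0.890 and 0.890). Dendritic cell, mast cell and endothelial markers had medians of 0.25, 0.35 and 0.20 (adjusted p = 0.0849, 0.0972 and 0.0972), and all 3 lists passed as higher without GRwt replicate 1 (0.29, 0.61 and 0.31). They also passed as higher without GRdim replicate 3 (dendritic, 0.31), GRdim replicate 1 (mast, 0.60) and GRdim replicate 2 (endothelial, 0.44). With no library left out, the mast cell list passed with DESeq2, limma-voom, DESeq2 with the T as a covariate and GRdim replicates 1 and 3 summed (adjusted p = 0.00561, 0.0488, 0.0137 and 2.41e-04), and the endothelial list with DESeq2 without and with that covariate (adjusted p = 0.00700 and 0.0137). Tuft cell markers (median 0.26, adjusted p = 0.107) passed as higher without GRwt replicate 2 or GRdim replicate 3 (0.42 and 0.40), with no filter on low counts and with GRdim replicates 1 and 3 summed (adjusted p = 0.0449 and 0.0184). Enteroendocrine markers (median -0.14, adjusted p = 0.132) passed as lower without GRwt replicate 1 or GRdim replicate 1 (-0.23 and -0.53). Immediate early genes (median -0.04, adjusted p = 0.171) passed as lower without GRwt replicate 3, GRdim replicate 2 or GRdim replicate 3 (-0.28, -0.19 and -0.30). Xenobiotic and retinoid metabolism genes (median -0.00, adjusted p = 0.675) passed as higher without GRwt replicate 2 or GRdim replicate 3 (0.31 and 0.14), and erythroid genes (median -0.27, adjusted p = 0.848) as higher without GRwt replicate 3 (0.60) and among the 4 libraries with no T in their names (0.54). Fibroblast and matrix genes (median 0.10, adjusted p = 0.675) passed as lower with limma-voom (-0.12), with GRdim replicates 1 and 3 summed (-0.09), without GRdim replicate 1 (-0.15) and among the 4 libraries with no T in their names (-0.18) but as higher without GRdim replicate 2 (0.36), and enteric neuron and glia markers (median 0.11, adjusted p = 0.890) as higher without GRdim replicate 2 (0.35) but as lower without GRdim replicate 3 (-0.19).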

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

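The fits on the 4 libraries with no T in their names, DESeq2 with the T as a covariate, and unadjusted p near Nr3c1 were chosen after the data were seen; all other alternatives were planned. The count of 0 genes past the threshold in edgeR (541 at an unadjusted p under 0.05) was 33 with DESeq2 (747 unadjusted) and 54 with DESeq2 and the T covariate (1141), with 30 genes shared; the cause was not tested. It stayed at 0 with relative log expression factors (531), no filter on low counts (648), limma-voom (903), the replicate block (355), the T covariate (785), GRdim replicates 1 and 3 summed (528), the 4 libraries with no T (1165), and each library left out (245 to 1048). With the replicate block 23 lists passed, the receptor target, colonocyte and endothelial lists in addition (medians -0.18, -0.08 and 0.22; adjusted p = 0.0248, 0.0178 and 0.00709). Nothing in the labels pairs the replicate numbers, and deviations from the group means were not positively correlated above 0.1 in any pair of the same number (r across genes of -0.39, 0.03 and -0.43, against up to 0.45 for unlike numbers). The number of lists past the threshold ran from 17 to 26 over all 15 alternatives. Of the 20 lists past the threshold 10 passed in every alternative and 10 were lost in at least 1; of the 19 others 14 passed in at least 1. With an estimated correlation 0 lists passed wherever that was run. The log2 fold change of Nr3c1 ran from -0.17 to 0.23 with 1 library left out and was -0.041 in the 4 libraries with no T, where the direction reversed with fewer samples. Near Nr3c1 0 genes passed with edgeR in windows of 5, 10 and 20 Mb, and 4 had an unadjusted p under 0.05 within 10 Mb; there DESeq2 called Spink6, and with the T covariate both Spink6 and Cd14 (adjusted p = 6.08e-07 and 0.00813). With 1 library left out the log2 fold change of Hsd11b1 ran from -0.95 to 0.068 (reversed without GRwt replicate 1) and that of Spib from -0.090 to 1.54 (reversed without GRdim replicate 2). Ddx3y ran from -6.43 to 6.69 (reversed without GRdim replicate 2, the library with Y-linked transcripts). Krt6a ran from -0.23 to 3.99, Krt10 from -0.15 to 3.83 and Lgals7 from -0.48 to 2.93 (all reversed without GRdim replicate 3, which held most of their counts). Where 1 library decided a value the other causes were not tested. For named genes other than Nr3c1, 1276 results kept direction and side of the threshold, 38 passed only under an alternative and 6 reversed. Not run were the sex covariate, planned only for the case of both sexes in both genotypes, and the alternatives planned for a table without counts.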

Other observations

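The explanations below were tested only after the result was seen, except for the number of lists over other splits and the posterior Hox genes without GRdim replicate 3; leaving out 1 library and the T as a covariate in edgeR were planned fits. Transcripts of endoplasmic reticulum chaperones, which fold secreted proteins, were lower in GRdim tumors. Hspa5, the main chaperone of that compartment, stood at 1082 ± 111 CPM in GRwt and 688 ± 75.1 CPM in GRdim tumors, and the disulfide isomerases Pdia4 and Pdia6 at 319.9 ± 54.8 and 427 ± 37.8 against 215 ± 1.198 and 277 ± 37.2 CPM. Sdf2l1, a component of the same chaperone complex, stood at 72.3 ± 22.3 against 45.1 ± 5.65 CPM. In a list of 22 such genes 21 were lower, 11 of them at an unadjusted p under 0.05 with edgeR, with a median log2 fold change of -0.40. None passed when adjusted over all genes, and Dnajb9, Sel1l, Atf4, Ddit3, Atf6 and Herpud1 had log2 fold changes between -0.07 and -0.01. Camera with an estimated correlation gave the list alone p = 0.0448, a value that was 0.299 after adjustment over all lists. A coordinated lower level of these transcripts may exist and remains a hypothesis found and tested on the same samples.

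Receptor targets went both ways. Of the fixed target list 37.1% of the tested genes were higher in GRdim tumors, Sgk1 and Per1 among them, whereas Lcn2 and Cebpb were lower. Per1 was chosen after its values were seen.

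Lower neutrophil and inflammatory cytokine transcripts were weighed first against a general loss of leukocytes or dilution by other tissue. Either would lower the leukocyte lists alike, unless the other tissue brought leukocytes of its own. Instead the neutrophil score minus the mean of the macrophage, T and NK, and B cell scores differed by -1.61 (GRdim minus GRwt) on the log2 scale (standard error 0.47), the single scores having moved by -1.01, 0.01, 0.39 and 1.37. The neutrophil markers had been picked for their small p in this comparison, and B cell scores varied within GRwt (SD 1.83), so the size of this gap is uncertain. Dilution by tissue with its own macrophages or lymphocytes is not excluded by it. The median log2 fold change of both lists together was -0.80 in all libraries, -0.86 in the 4 libraries with no T in their names and -0.85 in the pair with it. That of the inflammatory list alone was -0.58, -0.34 and -0.44. Each genotype held a library with a T, and both lists had been picked for their small p on all libraries. Lower medians in parts of the same libraries therefore do not decide whether that library set had a part in the change or its size. The median of both lists together was -0.70 without GRdim replicate 3 and -0.90 without GRdim replicate 2, the library with Y-linked transcripts, so neither alone carried it. Fewer transcripts of recruited neutrophils in GRdim tumors may follow from the genotype, but differences in colitis severity, tumor stage or dissection between so few samples remain open and untested.

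Over the 10 splits of the 6 libraries into groups of 3, that median lay 0.80 from 0 for the genotype split and at most 0.43 for any other, so 1 split of 10 was as far; both lists had been picked for their small p in the genotype split, so this comparison does not bear on chance. The genotype split gave 541 genes at an unadjusted p under 0.05 with edgeR, and 7 of the 10 splits, the real one included, gave as many, the highest other being 2960. For DESeq2 calls the real value was 33, the highest other 708, and 5 splits gave as many. For lists the real value was 20, the highest other 23, and 3 splits gave as many. The 10 splits are too few for a share under 0.05. The 4 splits that put both T libraries in 1 group gave 1680, 2960, 855 and 2616 genes at an unadjusted p under 0.05 and 115, 708, 47 and 479 DESeq2 calls, which points to a structure of the samples other than genotype. Apart from the genotype split, those with the T libraries in different groups gave 503, 549, 283, 94 and 576 such genes and 9, 1, 4, 0 and 21 DESeq2 calls. With the T as a covariate DESeq2 called 54 genes for genotype and edgeR 0 (785 at an unadjusted p under 0.05).

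Squamous, smooth muscle and posterior Hox transcripts were weighed next, since GRdim replicate 3 stood out in all 3. Krt14, Krt10 and Krt6a, abundant keratins of stratified epithelium, stood at 341, 142 and 60.9 CPM there; of the 11 squamous markers 9 also reached 1 CPM in every GRwt library and 0 were in another list. Without that library the squamous median was -0.23, so squamous tissue in that sample, for example from the anal margin, is a candidate source; Krt4, higher in all 3 GRdim libraries, is not covered by it. Without it the smooth muscle median was 0.56 and the Hox median 0.45, so for these lists tissue content of that sample and a difference between genotypes cannot be told apart, because 1 of the remaining GRdim libraries lies within the GRwt range and 1 above it for each list. No biological explanation was tested, since the labels give no position of the tumors along the colon.

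Lower Spink6 was weighed last. Sequence linked to the altered Nr3c1 locus could alter nearby genes, Spink6 lying 4.66 Mb away. Genes within 10 Mb had an unadjusted p under 0.05 in 4 of 194 cases (one-sided Fisher exact p = 0.815), and the interval of that share includes the share of other genes, so linked sequence acting on few genes and an effect of the receptor cannot be told apart. Reads assigned to a related gene would raise another Spink gene on the chromosome, and 0 of those tested were higher in every GRdim library. Spink1 and Spink5 had log2 fold changes of -0.36 and 1.501 with overlap between genotypes. Spink6 held only 2.33 CPM in GRwt tumors, while Spink1 stood at 243 ± 76.3 CPM there and 189 ± 99.7 CPM in GRdim tumors. A gain of that size would not show in Spink1, so reads moved to it are not excluded. Spink5 stood at 1.42, 1.25 and 7.24 CPM in GRdim replicates 1, 2 and 3 against 1.17 ± 0.704 CPM in GRwt tumors.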
